A study of Homo sapiens with 12 samples.

How the data were processed

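RNA of HK-2 cells was hybridised to 12 Affymetrix arrays that carry probe sets for the whole human transcriptome, in 4 groups of 3: Aa at a low dose and control, at 24 h and at 48 h. The numeric dose, the full name of Aa and the control's vehicle are not given in the sources used here. According to the submitters' processing notes the arrays were normalised with GCRMA, whose version is not stated. The deposited values are on a log2 scale: they run from 0.82 to 16.25, which fits log2 intensities and not linear ones. All value columns of the table were matched to a sample. For arrays, their number limits the precision. The labels call the arrays biological replicates without saying how the cultures differed, so p-values measure the spread between these samples.

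The table holds 54675 probe sets, 62 of them controls. Gene names came from a map of probe sets to genes: 41097 probe sets had 1 symbol and were used, 1801 had several, and 11777 had no entry. Through the gene identifiers 41043 symbols were set to their current form in the GRCh38.p14 annotation, and 54 were not found there and kept. Probe sets with a mean log2 value of at least 4 over all 12 arrays were kept (41.3% of all, 19623 of those with 1 symbol), and each gene was represented by its probe set with the highest mean. This left 10791 of 19775 genes for testing. Of these, 5263 had several probe sets past the filter. The span of a gene, its length from start to end in the GRCh38.p14 annotation, was used as a property only, and 99.9% of the genes tested had a span. No coordinates are given, since no build is named for the array.

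The comparisons, tests, filter, threshold, gene lists, rule for named genes and most alternatives were set before the data were examined. A linear model of 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend. It had 8 residual and 2.76 prior degrees of freedom. The contrasts were Aa against control at 24 h and at 48 h, their difference (interaction), and control cells at 48 h against 24 h. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called changed. All tests were two-sided. In the text, rose and fell are used for genes past this threshold.

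Gene lists, 34 in number with 649 symbols, were written from general knowledge; 584 symbols had a probe set and 480 were tested. Target lists were those of p53, NRF2, ATF4, NF-kB, interferon-stimulated, hypoxia and aryl hydrocarbon receptor genes. Stress and growth lists were ER chaperones, heat shock proteins, metallothioneins, mitosis, DNA replication, DNA repair and histone genes. Metabolic and synthesis lists were cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis, oxidative phosphorylation, ribosomal protein, ribosome biogenesis, proteasome and lysosome genes. The remaining lists were apoptosis, immediate early, EGFR, TGF-beta and glutathione S-transferase genes, kidney injury markers, and markers of proximal tubule, distal nephron, fibroblasts, endothelium and leukocytes. The 30 lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Counts adjusted over the list alone used the Benjamini-Hochberg method within the list. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move one way without comparing them to other genes, were alternatives.

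Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes in which all 3 Aa arrays lay on the same side of all 3 control arrays, for each time. For the interaction (without the condition on arrays) and for the controls over time, they were the 5 largest in each direction. For each list they were up to 4 members with the smallest p. Genes outside the rule are said to have been chosen after their values were seen.

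The labels do not say whether replicates of the same number belong together. After subtracting group means, the 18 pairs of arrays with the same number correlated with r from 0.35 to 0.62 and the 36 pairs with other numbers from -0.49 to -0.01, and 12 of 12 arrays were closest to an array of their own number. A pairing is thus read from the data, and the replicate number was used as a block in an alternative fit. For the genes and lists described in a comparison, blocked values are given where they change a call or move a count by over 1.5 times. For a list they are given as genes up and down once either count moved so.

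The code was tested on simulated data with the spread of the real genes, 10791 genes and 200 of them changed, besides a planted list of 30 genes. At 24 h it recovered 43.3%, 83.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 24 false among 188 calls. At 48 h the shares were 43.3%, 79.1% and 93.9% (6 false among 161 calls), for the interaction 7.5%, 46.3% and 89.4% (3 among 99) and for the controls over time 32.8%, 65.7% and 95.5% (15 among 156). False calls thus made up 12.8% and 9.6% of the calls in the first and last of these simulations, above the nominal 5%. The planted list was called in all 4 comparisons and 0 of 29 random lists. The simulated values were drawn independently, without correlation between genes and without pairs of replicates. The simulation therefore does not show how often lists of correlated genes are called falsely. In each simulation far fewer genes changed than the 2494 and 4083 called in the real data at 24 h and 48 h. The shares recovered there may therefore differ.

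The alternatives changed one choice at a time, except for the estimated correlation on the blocked fit, which changed the model and the correlation together. For probe sets these were no filter or a mean of at least 6, the mean of a gene's probe sets, no probe sets marked as shared between sequences (_x_at and _s_at), and each probe set tested by itself. For arrays and model they were median centring, quantile normalisation, a variance trend with robust estimation, array weights, only the groups compared, the replicate block over all arrays or within each time, each array left out, and all arrays of a number left out. Scalings moved the median change of all genes by less than 0.1. Probe sets with several genes or no entry were left out of the gene tests, and part of the list symbols was not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.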

Results

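Messenger RNA was measured on 12 whole-genome oligonucleotide arrays in HK-2 cells, an immortalised human cell line derived from the proximal tubule of the kidney. Cells had been exposed to a low dose of a compound that the labels call Aa, or left as controls, for 24 h or 48 h. Each of the 4 groups held 3 arrays, which the labels call biological replicates. The series belongs to a larger study of several compounds that looked for expression signatures of toxicity. The questions here were which genes low-dose Aa changed at each time and whether its effect changed with time. Changes are log2 differences, Aa minus control, with the standard error (SE) of the limma model, and n = 3 arrays per group throughout.

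The arrays resembled each other closely. Pearson's r across probe sets was 0.994 to 0.997 between arrays of the same group and 0.98 to 0.992 between Aa and control arrays of either time. The actin control probe sets, whose signal at the 3′ end minus that at the 5′ end grows as RNA degrades, differed by 0.80 ± 0.10 (SD, n = 3) in the 24 h controls and 0.82 ± 0.16 in the 24 h Aa arrays, and by 0.78 ± 0.19 and 0.90 ± 0.22 at 48 h. The Aa array had the larger difference in 3 of 3 replicate pairs at 48 h, by 0.07 to 0.17. The same measure on the GAPDH control probe sets was higher with Aa by 0.02 at 24 h and by 0.01 at 48 h, in 2 of 3 pairs each time. Probe sets for 28S ribosomal RNA, by the array maker's names, were higher with Aa by 1.37 at 24 h and by 1.22 at 48 h, and in 3 of 3 replicate pairs each time. Array replicates with the same number resembled each other across groups, so that the number acts as a pairing. In the Aa arrays numbered 2 the changes were smaller, with slopes of 0.65 at 24 h and 0.72 at 48 h on the mean change of the other pairs, against 1.01 to 1.10 for the others.

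After 24 h with Aa, GCNA, which encodes a germ cell nuclear protein, had the largest measured rise, from 5.33 ± 0.51 (SD, n = 3) in controls to 10.22 ± 0.26, a 29.6-fold rise (log2 change 4.89, SE 0.30, adjusted p = 8.78e-06 in limma). LCT, the gene of the gut enzyme lactase, rose by 4.31 (SE 0.25), OIT3 by 4.36 (SE 0.45) and NEB, which encodes the muscle protein nebulin, by 3.87 (SE 0.32). Of the 10 named genes that rose, all but GCNA and IL20RB, 8 in number, had control means of 2.22 to 3.49, below the filter value of 4, so the size and the order of these rises are less certain than their direction. CEL, which encodes a lipase and was measured by 2 probe sets that both rose, gained 3.76 (SE 0.88, adjusted p = 0.0115). Its adjusted p ranged from 6.57e-05 to 0.178 over 24 alternative settings and missed the threshold in 2 of them. LINC01963, ANKRD18A, SLC6A16, CFAP251 and IL20RB were the other named genes that rose, by 3.63 to 4.14.

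IFI35, an interferon-induced gene, had the largest measured fall, 4.18 (SE 0.26, adjusted p = 1.07e-05), from 8.24 in controls to 4.06. NANOS1 (-4.03, SE 0.36), NLGN1, which encodes a synaptic adhesion protein (-3.80, SE 0.57), TRPT1 (-3.64, SE 0.47) and TSPAN31 (-3.59, SE 0.41, 2 of 2 probe sets) followed. NLGN1 lost its call in 1 alternative setting, with adjusted p from 2.44e-05 to 0.0519. The falls of TLCD1, ULK4, MPI, NFE2L3 (2 of 2 probe sets) and TDRKH ranged from -3.40 to -3.08. NANOS1, NLGN1, ULK4, MPI, NFE2L3 and TDRKH, 6 of these 10, had Aa means below the filter value, from 2.84 to 3.97, so their falls are uncertain in size. In total 2494 of 10791 genes tested changed at 24 h (23.1%), 1108 up and 1386 down, and 267 and 411 of these by at least 2-fold. Of 1290 changed genes with several probe sets past the filter, all probe sets moved the same way in 806. Without probe sets marked as shared between sequences 1091 genes rose and 960 fell, and per probe set 2612 rose and 2477 fell. The lean to falls thus rests on the probe sets used. All 3 Aa arrays lay on the same side of all 3 control arrays in 2469 of the changed genes and in 40.5% of all genes tested, where chance gives 10%. With the replicate number as a block, which removes differences between the pairs, 4457 genes changed, among them all 2494. The count was 536 without replicate 1 and 824 without replicate 3 in all groups.

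Lists of DNA replication and mitosis genes shifted in opposite directions at 24 h with the preset correlation. Of 30 mitosis genes measured, 12 fell and 1 rose (16 and 2 when adjusted over the list alone, 20 and 2 with the block), with a median change of -0.36 and an adjusted p of 0.000368 in limma's camera (0.762 with an estimated correlation). KIF20A, a kinesin of late mitosis, fell by 1.26 (SE 0.13) and DLGAP5 by 1.09 (SE 0.14). CCNB2, which encodes a cyclin that drives entry into mitosis, fell by 1.00 (SE 0.14) and CENPE, a kinetochore motor, by 0.96 (SE 0.13). Among 29 DNA replication genes, in contrast, 11 rose and 0 fell (12 and 0 adjusted over the list alone, 15 and 2 with the block, median 0.26, adjusted p = 0.00063; 0.762 with an estimated correlation). E2F2, a transcription factor of S phase genes, rose by 1.85 (SE 0.17), the replication licensing gene CDT1 by 1.18 (SE 0.20), and the G1/S cyclins CCNE2 by 0.80 (SE 0.16) and CCNE1 by 0.67 (SE 0.11). Cholesterol synthesis genes were the third list to pass the test, with 8 of 17 genes down and 0 up (10 and 0 adjusted over the list alone, 13 and 0 with the block, median -0.54, adjusted p = 0.000368; 0.653 with an estimated correlation). Among them ACAT2 fell by 0.93 (SE 0.18), SQLE, a rate-controlling enzyme of the pathway, by 0.65 (SE 0.09) and LSS by 0.59 (SE 0.12). SC5D fell by 1.07 (SE 0.12) on its brightest probe set but read 1.02, a rise, without probe sets whose names mark shared sequence. With a correlation estimated for each list 0 of the 30 lists passed in camera, and 1 had an unadjusted p under 0.05. Over all alternatives the adjusted p ranged from 3.37e-05 to 0.832 for mitosis, from 2.05e-07 to 0.832 for replication and from 1.21e-05 to 0.832 for cholesterol synthesis.

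After 48 h with Aa, CEL (4.88, SE 0.88), GCNA (4.70, SE 0.30) and NEB (4.61, SE 0.32) had the largest measured rises, each of them named at 24 h too. AOC3, which encodes an amine oxidase, rose by 4.35 (SE 0.73), ALDH8A1, an aldehyde dehydrogenase gene, by 4.29 (SE 0.50) and WNK4, a kinase gene of renal salt handling, by 4.27 (SE 0.59). ZNF137P, SLC27A3, SHISA2 and IL20RB rose by 4.20 to 4.33. All but GCNA and SLC27A3, 8 of the 10, had control means of 2.24 to 3.68, below the filter value of 4, which leaves the size and the order of these rises uncertain.

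GPC6, which encodes a heparan sulphate proteoglycan, fell the most, from 9.41 in controls to 4.56 (log2 change -4.85, SE 0.62, adjusted p = 0.000278, 2 of 2 probe sets). ANK2, an ankyrin gene, fell by 4.28 (SE 0.68) and the mitochondrial peptidase gene IMMP2L by 4.14 (SE 0.46). TSPAN31 (-4.13, 2 of 2 probe sets) and TRPT1 (-4.00) were again among the named genes. DIAPH2 (-4.09, SE 1.07, 2 of 2 probe sets), LRMDA (-4.07, SE 0.71), SMYD3 (-4.05), SCFD2 (-4.04) and GPR160 (-3.98) completed them. DIAPH2 lost its call in 4 alternative settings, and LRMDA, SMYD3, SCFD2 and GPR160 each in 1. The changed genes numbered 4083 (37.8%), 1919 up and 2164 down, 493 and 725 of them by at least 2-fold. The groups lay apart in 48.4% of the genes tested, where chance gives 10%. Of 2048 changed genes with several probe sets past the filter, all probe sets moved the same way in 1572. Without replicate 1 in all groups 1549 genes changed, and 2322 without replicate 3.

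Long genes stood out among those that fell, more so at 48 h. In the GRCh38.p14 annotation 7 of the 10 named genes that fell at 48 h span more than 300 kb (GPC6 1191 kb, LRMDA 1129 kb, DIAPH2 920 kb), as do 3.1% of the genes tested. At 24 h 2 of the 10 named falls were that long, and the 10 had a median span of 9.9 kb against 30.5 kb for all genes tested. The class over 300 kb was singled out after its values had been seen. The 331 tested genes of that span had a median change of -0.54 at 24 h, when 91 fell and 10 rose, and of -1.05 at 48 h, when 225 fell and 7 rose. With the block, 175 fell and 16 rose at 24 h, and 255 fell and 14 rose at 48 h. Genes spanning 10 to 30 kb had medians of 0.01 and 0.13, and 11% and 12.5% of them fell, against 27.5% and 68% over 300 kb. Falls were not limited to long genes. Under 10 kb the medians were -0.06 and 0, and 393 genes (18.1%) fell and 6.9% rose at 24 h. At 48 h 20.7% of that class fell and 17% rose. In control cells the median of the 331 genes changed by 0.12 from 24 h to 48 h. Centring each array or quantile normalisation left the medians between -0.54 and -0.52 at 24 h and between -1.05 and -1.04 at 48 h. The medians of the arrays over all probe sets already lay between 2.93 and 3.01, so these scalings had little to change.

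**Figure D1:**
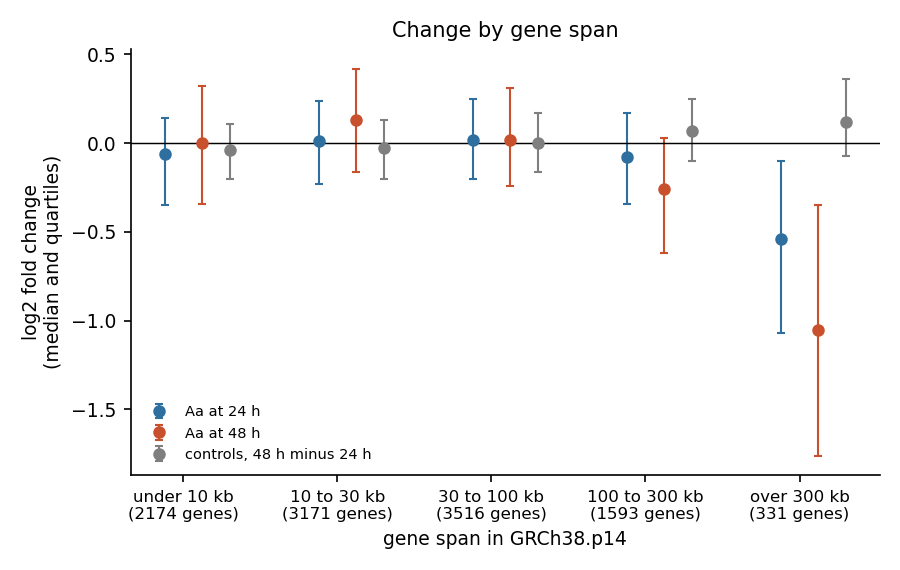
Median log2 fold change (points) with lower and upper quartiles across genes (bars) in 5 classes of gene span in GRCh38.p14, for Aa against control at 24 h and 48 h and for control cells from 24 h to 48 h. Genes over 300 kb lay at -0.54 and -1.05 with Aa and at 0.12 in the controls over time.

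At 48 h the mitosis genes were higher with Aa as a list. Of the 30 genes 23 rose and 0 fell (26 and 0 adjusted over the list alone; median 0.67, adjusted p = 9.8e-11 in camera; 0.834 with an estimated correlation). The topoisomerase gene TOP2A rose by 1.09 (SE 0.09), CDK1, the kinase that starts mitosis, by 1.04 (SE 0.11), KIF2C by 1.08 (SE 0.12) and the proliferation marker MKI67 by 1.07 (SE 0.13). Of the DNA replication genes 14 rose and 3 fell (15 and 4 adjusted over the list alone; median 0.26, adjusted p = 0.0157; 0.834 with an estimated correlation). E2F2 was up by 2.53 (SE 0.17), MCM10 up by 1.74 (SE 0.22) and MCM6 was down by 0.82 (SE 0.13). Of 5 histone genes measured 4 rose (5 adjusted over the list alone; median 1.07, adjusted p = 0.0157; 0.834 with an estimated correlation). H1-2 rose by 1.62 (SE 0.19) and H2BC5 by 1.28 (SE 0.22).

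Part of the immediate early and NF-kB inflammatory genes rose at 48 h. Among 16 immediate early genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.73, adjusted p = 0.0131; 0.834 with an estimated correlation). ATF3 rose by 3.31 (SE 0.47), JUN by 1.08 (SE 0.16) and KLF6 by 0.91 (SE 0.10), while MYC fell by 0.99 (SE 0.14). Of 16 NF-kB inflammatory genes 6 rose and 0 fell (6 and 1 adjusted over the list alone, 9 and 2 with the block, median 0.54, adjusted p = 0.0399; 0.834 with an estimated correlation). TNFAIP6 was higher with Aa by 3.45 (SE 0.34), over a control mean of 2.86, below the filter value. Its mean with Aa was 5.85 at 24 h and 6.31 at 48 h, while that of controls went from 6.22 to 2.86. The difference at 48 h thus came mainly from the lower controls. TNFAIP3, which encodes an NF-kB inhibitor, rose by 1.57 (SE 0.30), the cytokine gene LIF by 1.31 (SE 0.19) and NFKBIA by 1.01 (SE 0.14). With an estimated correlation 0 of the 30 lists passed in camera and 0 had an unadjusted p under 0.05. The adjusted p over the alternatives ranged from 6.7e-19 to 0.902 for mitosis and from 0.000103 to 0.902 for replication. It ranged from 7.17e-05 to 0.902 for histones, from 0.000235 to 0.902 for immediate early and from 0.00628 to 0.902 for NF-kB genes.

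**Figure D2:**
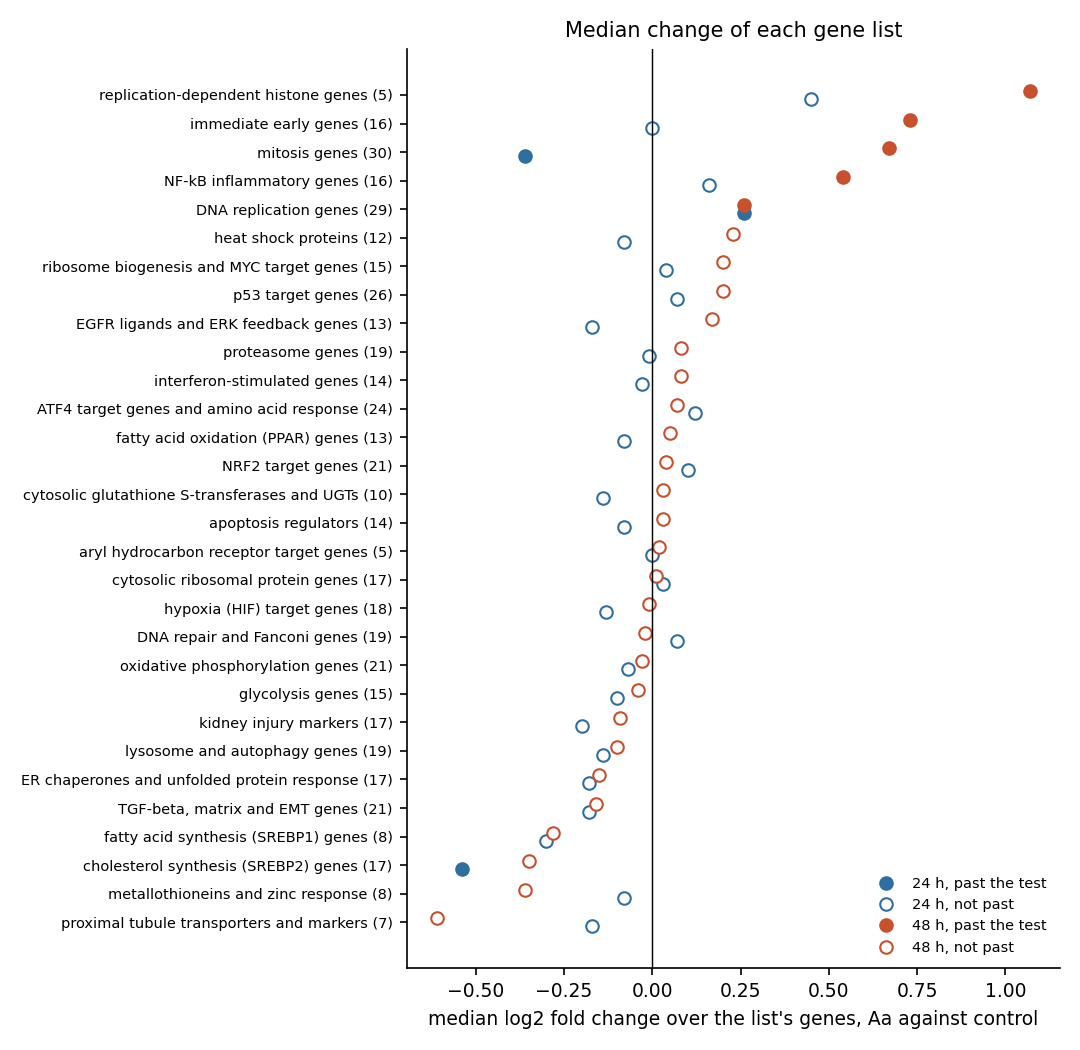
Median log2 fold change of the genes of each list, Aa against control, at 24 h (blue) and 48 h (orange), with the number of genes measured in brackets. Filled points passed the camera test with the preset correlation (3 lists at 24 h, 5 at 48 h), and the mitosis genes lay at -0.36 and 0.67.

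The proximal tubule list, 7 genes measured of a cell type that HK-2 cells derive from, had 4 genes down and 0 up at 48 h (the same adjusted over the list alone; median -0.61) and 0 changed at 24 h (3 down with the block, median -0.17, adjusted p = 0.569). CDH6, which encodes an adhesion protein of the renal tubule, fell by 1.48 (SE 0.24), the amino acid transporter gene SLC3A1 by 1.87 (SE 0.48), ABCC4 by 0.61 (SE 0.18) and the renal transcription factor gene PAX8 by 0.45 (SE 0.11). As a list it missed the threshold at 48 h, with adjusted p = 0.0836, and passed it with the replicate block, with adjusted p = 0.0159 (0.902 with the block and an estimated correlation). When the 48 h arrays were split into groups in other ways, another split reached a median of 0.73 in size, and 2 of 10 splits were as large as the real one. The metallothionein and zinc response list missed the threshold too, with 6 of 8 genes down at 48 h (the same adjusted over the list alone, median -0.36, adjusted p = 0.0637). All 6 encode metallothioneins, which bind zinc and other metals, and fell, MT1X by 0.48 (SE 0.10) and MT1F by 0.45 (SE 0.08). At 24 h 0 of 8 did (adjusted p = 0.728, and 1 up and 1 down with the block). Among 17 kidney injury markers KRT20, a keratin gene, fell by 2.38 (SE 0.62) at 24 h and by 3.51 (SE 0.62) at 48 h. In this list 2 fell and 0 rose at 24 h (adjusted p = 0.327) and 2 fell and 1, CD44, rose at 48 h (adjusted p = 0.812, and 4 and 4 with the block).

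Genes of the DNA damage response changed in both directions, and their lists did not pass camera, which tests a shift in one direction. CDKN1A, which encodes the p53-induced cell cycle inhibitor p21, rose by 1.03 (SE 0.22) at 24 h and by 1.66 (SE 0.22) at 48 h, and GADD45A rose by 1.03 (SE 0.15) at 48 h. The p53 targets TP53I3 (-2.23, SE 0.14, and -0.88, SE 0.14) and PLK2 (-0.90, SE 0.15, and -0.98, SE 0.15) fell at both times. Of 26 p53 targets 4 rose and 4 fell at 24 h (adjusted p = 0.728, and 5 and 7 with the block), and 8 rose and 5 fell at 48 h (adjusted p = 0.506). Of 19 DNA repair genes 8 rose and 4 fell at either time (adjusted p = 0.569 and 0.506). That is a larger share changed than over all genes tested, 23.1% at 24 h and 37.8% at 48 h, as was that of the p53 targets. Whether these shares differ was not tested. The excision repair gene ERCC1 fell by 1.29 (SE 0.12) and 1.33 (SE 0.12), while BLM, a helicase gene, rose by 0.85 (SE 0.15) and 1.03 (SE 0.15). Among 14 apoptosis regulators 1 fell at 24 h (adjusted p = 0.938, and 2 up and 3 down with the block). At 48 h PMAIP1 rose by 1.57 (SE 0.27) and 3 fell, BCL2 by 1.43 (SE 0.46), with adjusted p = 0.987 for the list and 4 up and 3 down with the block.

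Stress and nutrient lists also held changes without passing the list test, and counts with the block are given as up and down. Over all genes tested 23.1% changed at 24 h and 37.8% at 48 h (4457 and 5917 of 10791 with the block). Without the block the counts of the ATF4, NRF2, ER chaperone and heat shock lists lay below these shares at both times. Counts near or below them, here and in the lists that follow, do not set a list apart from all genes. Of 24 ATF4 targets 4 rose and 1 fell at 24 h (adjusted p = 0.25, and 7 and 3 with the block), where STC2 rose by 1.41 (SE 0.25). At 48 h 4 rose and 5 fell (adjusted p = 0.826, and 7 and 7 with the block), and the cystine transporter gene SLC7A11 fell by 2.69 (SE 0.52). Of 21 NRF2 targets 3 rose and 0 fell at 24 h (adjusted p = 0.394, and 6 and 3 with the block), TXNRD1 by 0.51 (SE 0.10), and 2 rose and 4 fell at 48 h (adjusted p = 0.859). Among 17 genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response 0 rose and 2 fell at 24 h (adjusted p = 0.111, and 0 and 6 with the block), HERPUD1 by 0.43 (SE 0.10), and 2 rose and 4 fell at 48 h (adjusted p = 0.757, and 4 and 6 with the block). Of 12 heat shock genes 0 rose and 2 fell at 24 h (adjusted p = 0.622, and 1 and 2 with the block), HSPA4L by 0.68 (SE 0.17), and 4 rose and 0 fell at 48 h (adjusted p = 0.111, and 7 and 0 with the block), BAG3 by 0.53 (SE 0.11). Of 18 hypoxia targets 3 rose and 3 fell at 24 h (adjusted p = 0.665, and 3 and 7 with the block), and 4 rose and 6 fell at 48 h (adjusted p = 0.826), with ANGPTL4 up by 3.00 (SE 0.41) and ADM by 2.37 (SE 0.40). The lysosome and autophagy list of 19 genes had 1 up and 3 down at 24 h (adjusted p = 0.541, and 2 and 5 with the block) and 4 up and 6 down at 48 h (adjusted p = 0.757). The lysosomal channel gene MCOLN1 rose by 0.68 (SE 0.17) and 1.21 (SE 0.17).

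In lipid metabolism, ELOVL6, which encodes a fatty acid elongase, fell by 1.74 (SE 0.17) at 24 h and by 1.60 (SE 0.17) at 48 h. Of 8 fatty acid synthesis genes 0 rose and 3 fell at 24 h (adjusted p = 0.199, and 0 and 5 with the block), and 1 rose and 4 fell at 48 h (adjusted p = 0.258). Fatty acid oxidation genes, 13 in number, went both ways, with 3 up and 3 down at 24 h (adjusted p = 0.742) and 4 up and 1 down at 48 h (adjusted p = 0.738, and 6 and 2 with the block). The lipid droplet gene PLIN2 rose by 0.80 (SE 0.15) and 1.18 (SE 0.15). The cholesterol synthesis list no longer passed at 48 h (adjusted p = 0.25), where 7 genes fell and 0 rose (8 and 1 with the block), INSIG1 by 1.01 (SE 0.19). Of 15 glycolysis genes 1, PFKM, fell at 24 h (adjusted p = 0.327, and 3 with the block) and 4 at 48 h (adjusted p = 0.506). Oxidative phosphorylation, 21 genes, had 2 down at 24 h (adjusted p = 0.327, and 4 with the block), and 1 up and 4 down at 48 h (adjusted p = 0.812, and 4 and 4 with the block), UQCRC2 by 0.38 (SE 0.10) and 0.35 (SE 0.10).

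Signalling lists were mixed. TGF-beta, matrix and EMT genes, 21 in number, had 4 down at 24 h (adjusted p = 0.225, and 7 with the block), CCN2 by 0.99 (SE 0.21), and 3 down at 48 h (adjusted p = 0.757, and 3 up and 8 down with the block). Of 13 EGFR ligand and ERK feedback genes 2 fell at 24 h (adjusted p = 0.578, and 1 up and 3 down with the block), SPRY2 by 0.81 (SE 0.19), and 3 rose and 2 fell at 48 h (adjusted p = 0.826, and 4 and 5 with the block), the ligand gene HBEGF rising by 2.98 (SE 0.42). At 24 h the immediate early list had 2 up and 2 down (adjusted p = 0.653, and 5 and 2 with the block), EGR1 falling by 1.40 (SE 0.25), and the NF-kB list 2 up and 0 down (adjusted p = 0.453). Of 14 interferon-stimulated genes 1 rose and 2 fell at 24 h (adjusted p = 0.938, and 3 and 4 with the block), and 4 rose and 2 fell at 48 h (adjusted p = 0.757, and 5 and 5 with the block), OAS3 up by 1.45 (SE 0.17). Of 5 aryl hydrocarbon receptor targets CYP1B1 rose by 0.67 (SE 0.21) at 24 h (adjusted p = 0.988 for the list, and 1 up and 1 down with the block). It rose by 0.61 (SE 0.21) at 48 h, when 2 others fell (adjusted p = 0.825). Of 10 glutathione S-transferase and UGT genes 2 fell at 24 h and 2 at 48 h (adjusted p = 0.541 and 0.826, and 2 up and 4 down with the block at 48 h), GSTM3 by 0.52 (SE 0.15) and 0.90 (SE 0.15).

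Of 17 ribosomal protein genes 1, RPS27L, fell by 0.39 (SE 0.09) at 24 h (adjusted p = 0.691), and 0 passed at 48 h (adjusted p = 0.849, and 1 down with the block). Of 15 ribosome biogenesis and MYC target genes 2 fell at 24 h (adjusted p = 0.938, and 1 up and 2 down with the block), and 2 rose and 2 fell at 48 h (adjusted p = 0.613, and 8 and 2 with the block), ODC1 up by 0.82 (SE 0.14). Of 19 proteasome genes 0 passed at 24 h (adjusted p = 0.939, and 1 up and 1 down with the block), and 2 rose and 1 fell at 48 h (adjusted p = 0.506, and 6 and 1 with the block). The 5 histone genes had a median of 0.45 at 24 h, where 0 passed (adjusted p = 0.25, and 1 up with the block). Lists of other cell types were too short for a set test. Of 2 distal nephron, 3 fibroblast and 1 endothelial gene measured only the collagen gene COL1A1 passed, by -0.85 (SE 0.24) at 24 h, and 0 leukocyte genes passed the signal filter. With the block 1 distal nephron gene passed upward at each time, and of the fibroblast genes 2 passed downward at 24 h and 1 each way at 48 h.

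Adjusted over the list alone, the counts of the lists not past the test stayed as given, with these exceptions. At 24 h the changes were 0 up and 0 down for oxidative phosphorylation and for apoptosis, 0 and 1 for kidney injury and 1 and 0 for NF-kB. They were 3 and 2 for immediate early, 3 and 4 for hypoxia, 2 and 2 for interferon-stimulated and 0 and 2 for fibroblast genes. At 48 h they were 9 and 5 for p53, 5 and 5 for ATF4, 9 and 4 for DNA repair, and 4 and 3 for interferon-stimulated genes. For metabolic and organelle lists they were 0 and 3 for glycolysis, 0 and 2 for oxidative phosphorylation, 1 and 1 for ribosome biogenesis, 5 and 6 for lysosome and 0 and 1 for glutathione S-transferase genes. The median, the mean and the direction of the test differed in sign for some lists far from the threshold. At 24 h the test read up beside a mean of -0.06 and a median of 0.07 for p53 targets and a mean of -0.13 and a median of -0.03 for interferon-stimulated genes. It also did so beside -0.01 and 0.04 for ribosome biogenesis and -0.03 and -0.01 for the proteasome, and it read down beside a mean of 0.01 and a median of -0.08 for fatty acid oxidation. At 48 h it read up beside a mean of -0.10 and a median of 0.04 for NRF2 targets, -0.05 and 0.08 for interferon-stimulated genes and 0.17 and -0.02 for DNA repair. It read down beside a mean of 0.13 and a median of -0.01 for hypoxia, -0.15 and 0.02 for aryl hydrocarbon receptor targets and -0.13 and 0.03 for glutathione S-transferases.

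The changes of the 24 h and 48 h arrays, which share no control array, overlapped. Of the changed genes 825 rose at both times and 993 fell at both, where independent lists of those sizes would share 197 and 278. A further 18 genes changed in opposite directions, 658 passed at 24 h alone and 2247 at 48 h alone. With the replicate block 1442 rose at both times and 1782 fell at both, 3224 against 1818 without it, while 114 changed in opposite directions and 1119 passed at 24 h alone. Of the 18 genes without the block 5 belong to the list of 30 mitosis genes (AURKA, NDC80, NUF2, PTTG1 and TPX2), and of the 114 with it 14, a count made after their values were seen. Across genes the log2 changes at the times had r = 0.80 and Spearman's rho = 0.73; genes are not independent replicates, so no p is given.

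Whether the effect of Aa differed between the times was tested as an interaction. TNFAIP6, which encodes a hyaluronan-binding protein induced in inflammation, had the largest measured difference. Its change was -0.37 at 24 h and 3.45 at 48 h (difference 3.81, SE 0.48, adjusted p = 0.0179 in limma, 2 of 2 probe sets). With Aa its level was 5.85 at 24 h and 6.31 at 48 h. In controls it fell from 6.22 to 2.86, below the filter value of 4. CDKN2B at 48 h in controls (3.70) and SLC60A1 with Aa (3.46 and 3.35) lay below it too, so the size and the order of these 3 differences are uncertain. CDKN2B, which encodes the cyclin-dependent kinase inhibitor p15, differed from controls by 0.62 at 24 h and by 3.58 at 48 h (difference 2.96, SE 0.37). ENC1 followed with 0.20 and 2.81 (difference 2.61, SE 0.33, 2 of 2 probe sets) and SERTAD1 with a difference of 2.08 (SE 0.37). ID2, an inhibitor of basic helix-loop-helix factors, changed sides from -0.77 to 0.98 (difference 1.76, SE 0.24, 2 of 2 probe sets). EDIL3 (-1.70, SE 0.26), SLC60A1 (-1.24, SE 0.19), TMEM120A (-1.20, SE 0.17), WASF3 (-0.94, SE 0.17) and ZSCAN31 (-0.94, SE 0.18) went the other way. In all, 89 genes passed, 80 with a more positive change at 48 h and 9 with a more negative one, and 48 and 3 of them by at least 2-fold. This count rested on the spread between pairs and on single arrays: it was 1183 with the replicate block and 0 to 255 when 1 array was left out. Its lean to one side was not stable either, with 678 more positive and 505 more negative with the block, and 124 and 131 of the 255 without the 48 h Aa array numbered 2.

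**Figure D3:**
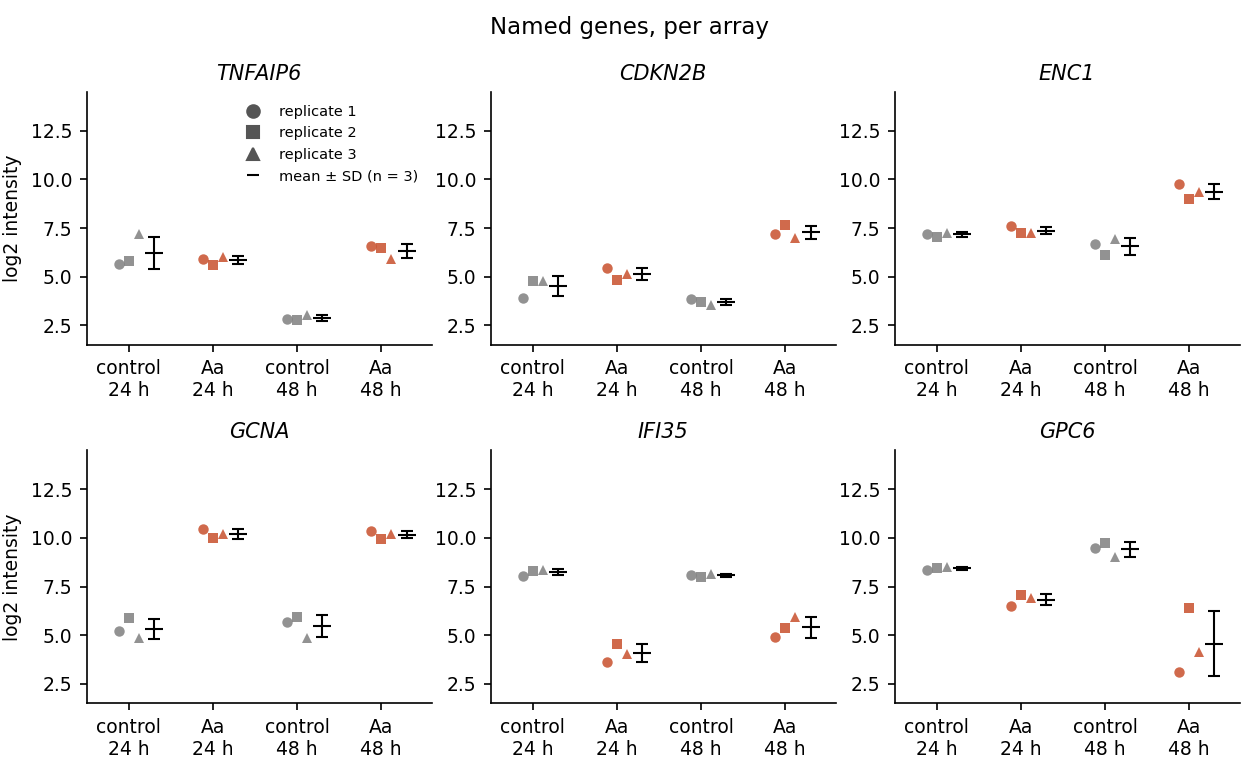
Log2 intensity of 6 named genes on each array (symbols by replicate number; bars, mean ± SD, n = 3) in control and Aa cells at 24 h and 48 h. TNFAIP6 fell from 6.22 to 2.86 in controls, GCNA lay at 10.22 with Aa against 5.33 in controls at 24 h, and GPC6 lay at 4.56 against 9.41 at 48 h.

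The mitosis list changed sign between the times. The difference of the Aa effects had a median of 1.06 over the 30 genes, 18 of which passed upward and 0 downward (30 and 0 adjusted over the list alone). Its adjusted p in camera was 6.14e-38, with adjusted p = 0.175 with an estimated correlation and a range of 7.92e-52 to 0.662 over the alternatives. KIF20A differed by 1.49 (SE 0.18), CENPE by 1.27 (SE 0.18), CENPF by 1.04 (SE 0.14) and TOP2A by 1.02 (SE 0.12). With the replicate block all 30 passed. The mean level of the list was 11.31 ± 0.17 (SD, n = 3) in controls and 10.93 ± 0.09 with Aa at 24 h, and 10.77 ± 0.16 in controls and 11.44 ± 0.06 with Aa at 48 h.

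**Figure D4:**
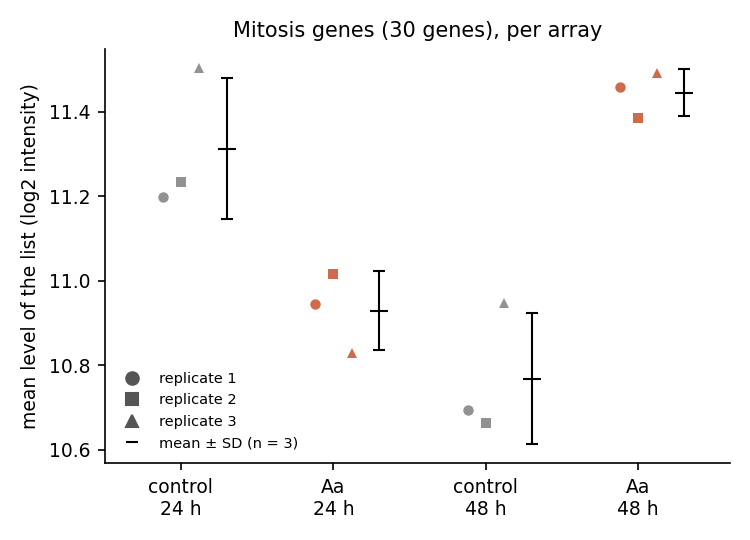
Mean log2 intensity of the 30 mitosis genes on each array (symbols by replicate number; bars, mean ± SD, n = 3) in control and Aa cells at 24 h and 48 h. Aa arrays lay below the controls at 24 h (10.93 against 11.31) and above them at 48 h (11.44 against 10.77).

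In the same test 6 other lists passed with the preset correlation. Immediate early genes had a median difference of 0.53 (adjusted p = 0.00092; 0.395 with an estimated correlation), heat shock genes of 0.32 (0.00106; 0.395) and NF-kB genes of 0.51 (0.0305; 0.519). The medians were, for cholesterol synthesis genes, 0.26 (0.0168; 0.395), for histone genes 0.29 (0.0266; 0.395) and for metallothionein genes -0.25 (0.0129; 0.477). Of their single genes only TNFAIP6 passed; adjusted over the list alone, 5 immediate early, 3 heat shock, 2 histone and 1 NF-kB gene did. With the block 6 immediate early, 4 heat shock, 6 NF-kB, 2 cholesterol synthesis and 1 histone gene passed upward, and 1 NF-kB and 2 proximal tubule genes downward. With the replicate block the histone list lost its call (adjusted p = 0.0744). The proximal tubule list gained one (median -0.44, adjusted p = 0.00697 with the block, 0.0693 without it, and 0.662 with the block and an estimated correlation). Of 100 relabellings of the times 19 gave this list a median as large, and the highest of the others was 0.91 in size.

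The controls alone gave the change with time in culture. TNFAIP6 (-3.35, SE 0.34, adjusted p = 0.00559 in limma), the collagenase gene MMP1 (-3.10, SE 0.26), INHBA, which encodes an activin subunit (-1.88, SE 0.33, 2 of 2 probe sets), AFAP1L2 (-1.70, SE 0.31) and DPYSL3 (-1.49, SE 0.25, 2 of 2 probe sets) fell from 24 h to 48 h. PLA1A (1.73, SE 0.30), FREM2 (1.51, SE 0.24), RAB17 (1.46, SE 0.25), CNN3-DT (1.39, SE 0.24, 2 of 2 probe sets) and BCO1 (1.27, SE 0.23) rose. At 48 h TNFAIP6 (2.86) and AFAP1L2 (3.86) lay below the filter value of 4, so the size and the rank of their falls are uncertain. In all 54 genes changed, 25 up and 29 down. In limma 0 passed when only the control arrays were fitted, where 1828 had an unadjusted p under 0.05, so these calls rest on the spread of all 12 arrays. The groups lay apart in 23.1% of genes, where chance gives 10%. With the block 1919 genes changed, and the count ran from 1 to 361 when 1 array was left out. Lists were tested on this comparison only after the reversal of the mitosis genes had been seen. Mitosis genes were lower at 48 h as a list (median -0.55, 2 down and 0 up, 27 and 0 adjusted over the list alone, 26 and 0 with the block, adjusted p = 8.3e-23; 0.308 with an estimated correlation). CCNA2 fell by 0.85 (SE 0.15) and PRC1 by 0.56 (SE 0.10). DNA replication genes were lower as well (median -0.35, 3 down and 0 up, 14 and 0 adjusted over the list alone, 15 and 0 with the block, adjusted p = 2.35e-12; 0.308). MCM10 fell by 1.21 (SE 0.22) and E2F2 by 1.06 (SE 0.17). Proteasome (median -0.23, adjusted p = 0.00073, and 0.663 with an estimated correlation), DNA repair (-0.32, 0.00252 and 0.358) and heat shock genes (-0.16, 0.0211 and 0.607) were lower as lists. Of their single genes 0 passed, and with the block 5, 7 and 2 fell and 0 rose. Adjusted over the list alone 6 DNA repair genes fell. ATF4 targets were higher (0.20, 0.00608 and 0.416), with adjusted p = 0.0501 under the block. Of these 1 rose and 0 fell (5 and 0 adjusted over the list alone, 5 and 1 with the block).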

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

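The tests of the controls' own change with time and of the poly-A spike-ins in this part were chosen after the results were seen, as were the list tests on the controls over time and the list medians over relabellings and the relabellings that part all pairs, and the tests of RNA integrity on ribosomal RNA; the others were planned.

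The mitosis genes drew attention because the test of the difference between the times passed: the median difference of the Aa effects was 1.06 (adjusted p = 6.14e-38 with the preset correlation and 0.175 with an estimated correlation). The lower level of these genes in the controls at 48 h, with a median of -0.55, is by definition a part of this difference. It is argued against as the whole cause, since the median in the Aa arrays themselves was higher at 48 h by 0.49, by 0.35 or more in each replicate number. A single replicate number is argued against as well, since the median was below 0 at 24 h and above 0 at 48 h in 3 of 3 numbers. Of 100 relabellings of the times, 1, the real one, gave a median difference of this size, and the highest of the others was 0.81. Of the 32 relabellings that part all pairs it was 1 again, with 0.79 as the highest of the others. The camera p does not set the real labels apart, since the list was called in 59 of 100. A candidate explanation is that Aa held cells before mitosis at 24 h, when replication genes such as E2F2 and CDT1 were higher, and that these cells divided or waited in G2 at 48 h. The replication list was not found to differ between the times, with a median of 0.26 at both (difference 0.05, adjusted p = 0.944 in camera). Of its 29 genes 0 passed the interaction, while with the replicate block 5 passed upward and 0 downward. Another candidate is that fewer cells with Aa may have left more room for growth at 48 h, while control cells crowded. Neither cell number nor cell cycle phase was measured on these arrays, so these stay open.

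The 6 other lists passed the same test of the difference, with medians of 0.53 for immediate early, 0.51 for NF-kB inflammatory, 0.32 for heat shock, 0.29 for histone, 0.26 for cholesterol synthesis and -0.25 for metallothionein genes. Each lost its call then (adjusted p = 0.395 to 0.519 with an estimated correlation). Chance could not be excluded for the number of lists, since 22 of 100 relabellings gave 7 or more lists, the real value, and the highest of the others gave 12. A median as large appeared in 3 relabellings for immediate early, 2 for heat shock, 2 for NF-kB, 17 for cholesterol synthesis, 32 for metallothionein and 49 for histone genes.

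Single genes whose Aa effect differed between the times were TNFAIP6 (3.81), CDKN2B (2.96), ENC1 (2.61), SERTAD1 (2.08), ID2 (1.76), EDIL3 (-1.70), SLC60A1 (-1.24), TMEM120A (-1.20), WASF3 (-0.94) and ZSCAN31 (-0.94). Of 100 relabellings 2 gave as many as the real 89. The other one called 659 genes, several times the real count; it exchanged the times in 1 arm only, so that it adds up a change with time that both arms share, and points to that structure. Against the 32 relabellings that part all pairs, as the real one does, it was 2 of 32, too many for a share under 0.05, so chance is not excluded for this count. The third highest of the 32 gave 1 gene. The replicate block gave 1183 genes.

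Ribosomal RNA lies outside the gene comparisons, yet its 28S probe sets were higher with Aa by 1.37 at 24 h and by 1.22 at 48 h, and its 18S probe sets by 0.62 and 0.36, each in 3 of 3 pairs. Less messenger RNA in the total RNA of the Aa samples would raise the poly-A spike-ins too, if these were added in a fixed ratio to total RNA, which is assumed here. The higher of their median changes was -0.20, and the pairs ran from -0.63 to 0.01. Under that assumption this argues against less messenger RNA. Degraded RNA is not tested by the spike-ins but by the 3′ minus 5′ signals of control probe sets. At 24 h it is argued against as the cause of the 28S values, since the pairs with actin changes of 0.00 and -0.01 had 28S changes of 1.52 and 1.47. The 3′ probe set of actin lay at 14.88 to 15.44, near the highest value of 16.25, which limits this test, though the actin signal did range from 0.63 to 1.15 over the arrays. At 48 h it stays open, since every actin change was positive, the smallest 0.07, while the GAPDH signal differed by 0.01. The GAPDH probe sets lay at 15.20 to 15.40, where the same limit holds. Carry-over of ribosomal RNA into labelling, or more ribosomal RNA per cell, may each remain, and no biological explanation was tested.

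Probe sets without a gene name, left out of the gene comparisons, changed too. Of 1932 of them past the signal filter, 454 changed at 24 h (324 up, 130 down) and 504 at 48 h (329 up, 175 down). The shares, 23.5% and 26.1%, were near that of the genes tested at 24 h (23.1%) and below it at 48 h (37.8%). With the replicate block the counts were 417 up and 283 down at 24 h, and 462 up and 329 down at 48 h.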

How the results depend on the processing

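The settings that leave out all arrays of a replicate number, the estimated correlation on the blocked fit and the list tests on the controls were added after the data were seen; all other settings were planned. Where no cause is given, the cause was not tested. Genes changed at 24 h, 2494, numbered 4457 with the replicate block, 4187 with the block within each time and 5089 per probe set, where more items were tested. They numbered 536 without replicate 1 and 824 without replicate 3 in all groups, where 8 arrays remained, and 1672 to 2628 with 1 array left out. At 48 h 4083 became 7485 per probe set, 1549 without replicate 1 and 2322 without replicate 3 in all groups, and 2971 to 4146 with 1 array out. The genes changed the same way at both times, 1818, became 3224 with the block, 3012 with the block within each time, 3587 per probe set, and 405 and 581 without replicates 1 and 3. With 1 array out they were 1280 to 1913. The interaction, 89 genes, gave 49 without shared-name probe sets, 168 with array weights, and 1183 and 841 with the blocks. It was 0, 6 and 1 without replicates 1, 2 and 3 in all groups, and 0 to 255 with 1 array out. It was 27 and 9 without Aa 24 h replicates 1 and 3, and 32, 0 and 1 without control 24 h replicates 1, 2 and 3. It was 1, 255 and 44 without Aa 48 h replicates 1, 2 and 3, and 0, 0 and 159 without control 48 h replicates 1, 2 and 3. The counts of 0 from limma stood beside 1525, 1317 and 1213 genes at an unadjusted p under 0.05 for single arrays and 808 without replicate 1. The controls over time, 54 genes, gave 94 with trend and robust estimation, 221 with array weights, and 0 with only the groups compared (1828 at an unadjusted p under 0.05 in limma). They gave 1919 with the block, 29 per probe set, and 1, 1 and 7 without replicates 1, 2 and 3. The block within each time could not be fitted. With 1 array out they were 1 to 361. They were 9 and 9 without Aa 24 h replicates 1 and 3, and 6, 2 and 3 without control 24 h replicates 1, 2 and 3. They were 8, 11 and 10 without Aa 48 h replicates 1, 2 and 3, and 1, 4 and 361 without control 48 h replicates 1, 2 and 3. The lists called at 24 h, 3, were 6 without a filter, 8 with fry, which asks another question, and 3 with any 1 array out. At 48 h 5 became 3 with a filter at 6, 3 without shared-name probe sets, 11 with fry, 1 without replicate 2 in all groups, and 4 to 6 with 1 array out. For the interaction 7 became 2 without shared-name probe sets, 3 with fry, 3 without Aa 24 h replicate 1, and 3 to 8 with 1 array out. An estimated correlation, with or without the block, left 0 lists in camera in all 3 comparisons. There were 1, 0 and 2 lists at an unadjusted p under 0.05 without the block and 0, 0 and 1 with it. The replicate block changed the call of no list other than those named in the report. Among 16 reversals of named genes, all came from the choice of probe set. Named genes with only shared-name probe sets past the filter, such as IFI35, TRPT1 and AOC3, could not be checked without these. Without shared-name probe sets ABCC3 read -0.047 at 24 h and -0.11 at 48 h (0.89 and 1.04 otherwise), SC5D 1.02 and 1.06 (-1.07 and -0.78), SULT1C2 0.44 and 0.42 (-1.20 and -0.95) and SDHC 0.059 at 48 h (-0.44). With the mean of a gene's probe sets HSPA5 read 0.18 at 24 h (-0.75), NDUFS1 0.24 and 0.048 (-0.42 and -0.56), WDR12 0.42 and 0.38 (-0.51 and -0.27), and CFLAR 0.36 and 0.19 (-0.58 and -0.75). At 48 h it gave SC5D 0.14 and PGK1 0.074 (-0.35). Of the other values of named genes 9712 kept direction and side of the threshold, 799 lost a call and 250 gained one. Of the lists' values 2453 stayed, 68 lost and 41 gained a call and 0 reversed. Genes and probe sets with weak signal are limited by the background of the arrays, and only 41.3% of probe sets passed the filter.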

Other observations

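All tests on genes over 300 kb, the set tests and other splits of long and of zinc finger genes, and the medians of lists over splits, were chosen after the results were seen; the tests of gene span over all genes and of zinc finger genes were written before their values but after the leading genes had been seen, and the splits for the counts were planned.

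Zinc finger genes rose more often than others. Of 341 tested genes whose symbol begins with ZNF, most of which encode DNA-binding transcription factors, 76 rose and 14 fell at 24 h (22.3% up, against 9.9% of other genes) and 113 rose and 25 fell at 48 h (33.1% against 17.3%; with the replicate block 122 rose and 25 fell at 24 h), with medians of 0.22 and 0.24 (0.22 to 0.25 under the scalings). The median was above 0 in each of the 6 pairs, with a lowest value of 0.09 at 24 h and 0.15 at 48 h. Their shorter genes, with a median span of 22.9 kb against 30.9 kb, are argued against as the cause: compared with other genes of the same span classes they were still higher by 0.18 at 48 h. In camera the set had p = 4.48e-07 and 1.08e-06, and 0.057 and 0.0641 with an estimated correlation. The largest median among the other splits was 0.13 at 24 h and 0.15 at 48 h, and 10 splits are too few for a share under 0.05. A longer life of these messages or a gain in their synthesis may each be involved; neither was tested.

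The tests of gene span over all genes gave a mixed answer. The rank correlation with span was -0.02 at 24 h and -0.20 at 48 h, where the pairs had -0.20, -0.17 and -0.19, and 0.16 in the controls over time. Across all genes a fall that grows with span in every pair was not found, since the highest rank correlation with span over the 6 pairs was 0.03. The test of RNA integrity used the pair with the smallest change of the actin 3′ minus 5′ signal, which had -0.05. That pair is of 24 h, when there was no trend to explain, so the test decides nothing and RNA integrity stays open for the trend at 48 h. Weak expression is argued against, with a rank correlation of -0.18 or lower in each of 5 classes of mean level at 48 h. Over 300 kb the pattern was clearer. RNA integrity is argued against as the cause at 24 h, since the median change was -0.65 in the pair with the smallest actin change, -0.01, and -0.69 in the pair with 0.00, while the third pair of that time, with 0.09, had only -0.25. The actin signal is high on these arrays, which limits this test. At 48 h the actin signal was higher with Aa in every pair and the GAPDH signal by 0.01 on average, so a part of the lower values then stays open. The pair with an actin change of 0.07 had a median of -1.24 and the pair with 0.17 one of -0.72. The latter, like the 24 h pair with 0.09, is replicate 2, whose changes were smaller over all genes (slopes of 0.65 at 24 h and 0.72 at 48 h). This contrast between pairs therefore cannot speak to RNA integrity. Weak expression is argued against at 48 h, where the median was -0.59 in the class with the highest signal (25 genes) and -1.37 in the lowest. At 24 h these medians were -0.10 and -1.01, so the brightest long genes had moved little by then.

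A candidate explanation is that Aa hinders transcription along the gene, so that the longest transcripts are lost first and more with time. In these data the median of genes over 300 kb was lower at 48 h than at 24 h in each replicate number, and the smallest further change was -0.47. This was written after the medians that prompted the explanation had been seen, so it describes the pattern and does not test the explanation. Of the single genes 2 of 331 passed the interaction downward and 0 upward (50 and 3 with the replicate block), so the growth with time rests on the median. DLC1 and KCNAB1, also over 300 kb and picked after their values were seen, rose by 1.17 (SE 0.22) and 1.23 (SE 0.36) at 48 h. Faster decay of these messages stays open, since levels alone do not separate it from lower synthesis. In camera the set had p = 5.37e-10 at 24 h and 7.2e-22 at 48 h, and 0.273 and 0.105 with an estimated correlation. Other splits of the arrays reached medians of 0.44 and 0.73 in size, and 10 splits are too few for a share under 0.05.

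Other splits of the arrays were run for each count. For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. At 24 h 1 split gave as many genes as the real 2494, the real one itself, and the highest of the others gave 0 in limma (48 to 1024 at an unadjusted p under 0.05). At 48 h it was 1 split with 4083 against 0 (46 to 1493), and for the controls over time 1 split with 54 against 1 (54 to 1399). By replicate number 4 of the 10 splits part all 3 pairs, the real one among them, and the other splits of that kind gave 0 genes at 24 h, at 48 h and in the controls. The remaining splits part 1 pair each and gave at most 0, 0 and 1 genes. For lists, 5 of 10 splits gave at least the real 3 at 24 h, with 5 as the highest other, and 4 of 10 at least the real 5 at 48 h, with 8 as the highest other. The mitosis list was called in 7 of 10 splits at 24 h and 7 of 10 at 48 h, though its median was larger in size in the real split (-0.36 and 0.67) than in any other (0.26 and 0.34). For NF-kB genes at 48 h another split reached a median of 0.60 in size, against the real 0.54, and 2 of 10 were as large.

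Of 10 leukocyte genes with a probe set 0 passed the signal filter, of 10 endothelial genes 1, of 14 distal nephron genes 2, among them CDH16 at a mean of 9.24, and of 11 fibroblast genes 3, among them DCN at a mean of 11.84. Of 24 proximal tubule genes 7 passed, with CDH6 at 12.21.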
